A study of Drosophila melanogaster with 191 samples.

How the data were processed

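The series holds polyadenylated RNA of Drosophila melanogaster midguts and whole flies, sequenced as stranded single-end libraries of 76 or 50 bases. Flies sequenced with 50 bases were kept on another food than those sequenced with 76 bases. The labels give sex, tissue, genotype, age, rearing, treatment, replicate number and read length, and these made 65 groups. They also give the ERCC spike-in mix. In 19 of the 21 comparisons of 76-base libraries, all but the axenic rescue at 7 d and dAdo against dGuo, the groups compared carried different mixes. The 2 interactions with sex have the same mixes in both sexes. In the others a batch that went with the mix cannot be told apart from the effect tested. Of the 191 libraries, 2 carry labels that contradict each other and were placed in no group. The planned comparisons left out treated axenic midguts, axenic yw midguts at 50 d, 50-base yw midguts at 40 d, whole females at 1 d or fed dAdo, and whole mutant males fed HU, which left 150 libraries in 51 groups.

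The authors aligned the reads with TopHat2 2.1.1 and made the gene counts with HTSeq 0.6.1p1, so the count values are whole numbers of reads per gene with no scaling, as deposited. The FPKM values were made by the authors with Cufflinks 2.2.1, which divides fragments by transcript length and by the total mapped, per the file headers. The genome build is not named in the labels. Of 17392 genes in both the Cufflinks tables and the BDGP6.54 annotation, 17137 had the same chromosome, start and end, and positions are given on that build. The count tables list 17402 genes, of which 17213 matched a symbol. Spike-in reads and the summary lines of HTSeq were set aside, and the total of counted reads over the genes is the depth of a library.

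Comparisons were run on the counts in R 4.3.3 with edgeR 4.0.16. Genes passed filterByExpr with its default settings, libraries were scaled by TMM, and a negative binomial model with 1 mean per group was fitted with robust quasi-likelihood dispersion and an F-test. A contrast over both sexes is the mean of the contrast in females and in males. Interactions are differences of such contrasts. An adjusted p from edgeR (Benjamini-Hochberg over the genes tested) under 0.05 is the threshold for a call. Each of the 36 comparisons was fitted with the other groups of its tissue, age and read length that its question needed, and read lengths were never mixed in a fit.

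Gene lists, 27 in number, were written before the data were examined. They cover pathways, gut cell types and tissues that dissection can carry over. Of their members 768 matched a gene counted and 8 did not (esg, Dl, hdc, Mcm3, Orc1, Top2, Pdi and nos), which rested on the spelling of symbols. Lists with at least 3 genes tested were compared with all other genes by camera in limma 3.58.1 on log2 CPM with a prior count of 2 and a preset correlation of 0.01. An adjusted p over the lists of a comparison under 0.05 is a call. The test was repeated with the correlation estimated from the data. Counts of list members are also given adjusted over the list alone.

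Genes are named by a rule. It takes AhcyL1, AhcyL2, RnrL and RnrS, along with y, w, lncRNA:roX1 and Yp1 as checks of the labels. It adds the called genes with the 8 highest and the 8 lowest fold changes in the main comparisons and the 3 highest and 3 lowest in the others. These need a mean of at least 5 CPM and all libraries of one group above all of the other within each sex. It also takes up to 4 called members of each list, or 2 of the most abundant where none is called. The text names some. Genes in the paragraph on the yw sets, the 4 genes that part mutant and rescue midguts from yw, the head genes Arr1, Arr2 and ninaE at other ages, and elav, nSyb, brp and the brain genes of the whole females were chosen after their values were seen.

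Overlaps of called lists are given beside the count for independent lists of those sizes. The rescue and the mutant comparison share the mutant libraries, so the correlation of their fold changes was also taken on data simulated with no change, in 20 runs, and with the mutant libraries parted between the comparisons.

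Groups, comparisons, tests, lists and the following alternatives were fixed before the data were examined. They were RLE scaling, no filter on low counts, DESeq2 1.42.0 with its own scaling and filter, replicate number as a block, each library left out in turn, and the estimated correlation in camera. After the data were seen, further alternatives were added. One was limma on log2 of FPKM plus 1 with a mean FPKM of at least 1. The other left out midgut libraries whose summed CPM on the fixed testis, ovary or head list was above 300. That rule and its limit were set after the sums were seen. They name 4 libraries. These are the 50-base mutant female replicate 1 at 1 d (head list, 365 CPM), the 76-base mutant female replicate 2 at 7 d (head, 1609 CPM), the rescue female replicate 3 at 7 d (ovary, 2149 CPM) and the yw male replicate 1 at 7 d (testis, 3051 CPM). The libraries were regrouped at random in up to 100 splits per comparison, and up to 60 in the axenic fits.

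A list of genes of the adult brain (Ilp5, SIFa, Hug, Pdf, Dsk, Rx and hbn) was also written afterwards, and SIFa, Rx and hbn had too few counts to be tested. So was the rule behind the yw sets. It asks that all libraries of one set lie above all of the other, that the means differ by at least 8-fold with 0.5 CPM added, and that the higher mean is at least 5 CPM.

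The edgeR step was tested on simulated counts for the 7 d comparison in 76-base midguts (9387 genes tested). It recovered 58% of genes changed 2-fold and 97% of those changed 4-fold and called 11 unchanged genes. For the 7 d comparison in 50-base midguts of females (9138 genes tested) it recovered 83% and 94% and called 5 unchanged genes.

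Over all 18145 pairs of the 191 libraries, no pair had identical counts, and the chi-square statistic per degree of freedom was at least 7.89, where copies of one sample would be near 1. It ran from 7.89 to 232.43 among 184 pairs of replicates, from 9.68 upward across groups, and from 104.09 upward between an unplaced and a placed library. In the groups compared, the number of libraries, 2 or 3, limits precision, and intervals cover the spread between libraries only.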

Results

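Polyadenylated RNA of Drosophila melanogaster was sequenced from dissected midguts and from whole flies of 3 genotypes. These were yw (the control stock, yellow white), a mutant of AhcyL1, and the mutant carrying a rescue transgene. AhcyL1 encodes a relative of S-adenosylhomocysteine hydrolase, the fly counterpart of mammalian IRBIT, a protein that restrains ribonucleotide reductase. Flies were sampled at 1, 7, 40 or 50 days (d) after eclosion. Some received deoxyadenosine (dAdo, 400 µM), deoxyguanosine (dGuo, 400 µM) or hydroxyurea (HU, 40 mM), a drug that blocks ribonucleotide reductase, and some were axenic, which means reared without microbes. The series held 191 libraries. Of these, 123 were 76-base midgut libraries in 43 groups, 30 were 50-base midgut libraries of females in 10 groups, and 18 each came from whole females and whole males in 6 groups each. The other 2 could not be placed in a group. The comparisons used 150 libraries in 51 groups. These held 3 libraries each, except 2 in axenic yw females, mutant males and rescue males at 40 d. The RNA lncRNA:roX1, made only in males, was at 158 CPM or more in every library labelled male and at 22.1 CPM or less in every library labelled female.

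The total of counted reads ranged from 2482454 to 21047773 per 76-base midgut library and from 5677046 to 33011601 per 50-base midgut library. It ranged from 8168031 to 44340100 in whole females and from 7026875 to 30808867 in whole males. Levels are given as CPM, counts scaled to the total of counted reads in a library, mean ± SD. Log2 fold changes are given with their standard error (SE) and a Benjamini-Hochberg adjusted p from edgeR. They rest on TMM scaling, so a ratio of CPM can differ from the fold change by -0.50 to 0.49 on the log2 scale. "Rose" and "fell" are used for genes with an adjusted p under 0.05. The p-values measure only the spread between these samples, since nothing in the labels says that libraries came from separate cultures. Gene positions are those of the BDGP6.54 annotation. Gene lists were tested as sets with camera, and of 306 calls with its preset correlation 13 held with an estimated one. The 13 are named where they occur, and other lists are given with the adjusted p that the estimated correlation left.

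AhcyL1 (FBgn0035371, 3L from 2768466 to 2772325) was lower in most libraries labelled mutant than in yw. In 50-base midguts of females it stood at 57.8 ± 8.81 CPM against 134 ± 12.6 at 1 d (n = 3 each) and at 79.8 ± 15.3 against 138 ± 15.1 at 7 d. Axenic mutants at 7 d had 62.4% of the yw level in females and 51.2% in males. Mutants at 40 d had 69.8% in females and 70.7% in males, and whole mutant males had 41.2%. Transcripts thus remained in every mutant group. In 76-base midguts at 7 d the libraries labelled mutant had 104.1% of yw in females and 84.9% in males. These percentages are on library totals. With TMM the fold change was negative in both sexes and did not pass (-0.36 in females, adjusted p = 0.3, -0.25 in males, adjusted p = 0.45, and over both -0.31 ± 0.12, adjusted p = 0.12, and 0.004 by DESeq2 to 0.86 by limma on FPKM). In whole females labelled mutant the level was 117.4% of yw. The rescue raised AhcyL1 above the mutant in every comparison, for instance to 174 ± 10.7 CPM in 7 d females and to 202 ± 13.1 in 7 d males. AhcyL2, another relative of the enzyme, fell by 0.46 ± 0.13 in 40 d mutant midguts (adjusted p = 0.0098, and 0.14 by limma on FPKM), by 1.01 in males and with no call in females (0.09, adjusted p = 0.76). It rose by 0.48 ± 0.14 in whole mutant males (adjusted p = 0.034), a call lost with a replicate block (0.053) and without any of 5 of the 6 libraries (0.063 to 0.14).

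**Figure D1:**
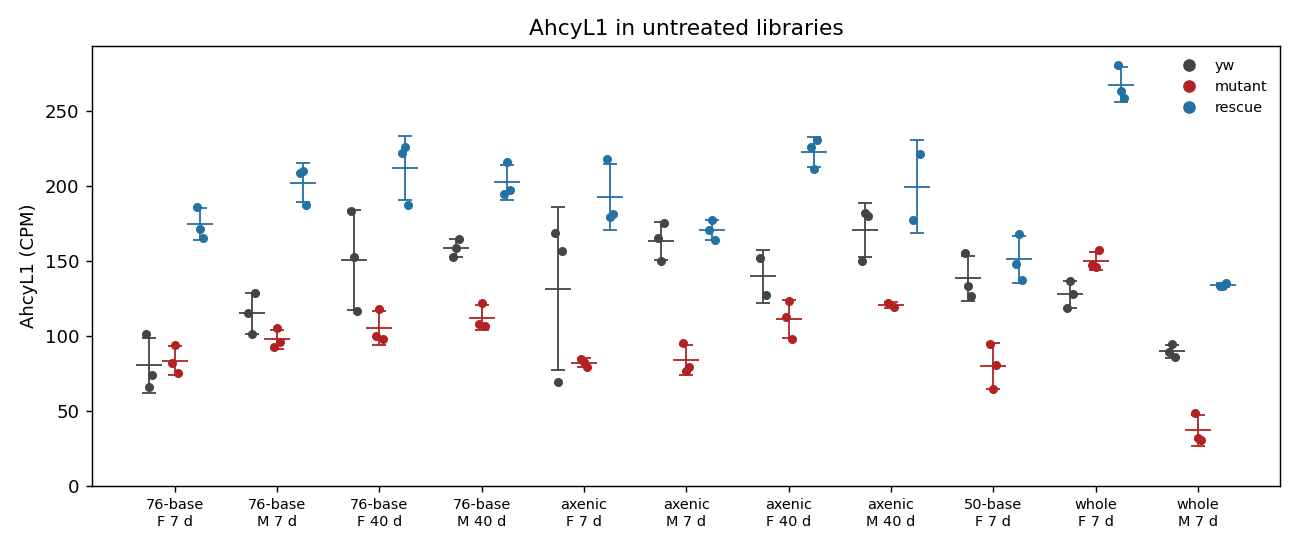
AhcyL1 in CPM in untreated libraries at 7 d and 40 d, by sex, age, rearing and tissue, with points for libraries and bars for the mean and SD of yw, mutant and rescue groups. On library totals, groups labelled mutant lay below yw except in 76-base females at 7 d and in whole females, where the means were 104.1% and 117.4% of yw. With TMM the changes there were -0.36 and 0.19, and neither passed.

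The yw libraries themselves fell into separate sets, which bears on every comparison of 76-base yw with another genotype or rearing. A rule chosen after these values were seen asked for genes that parted all 36 normally reared 76-base yw midguts from all 29 axenic ones by at least 8-fold, at 5 CPM or more in either set. It found 25 genes, 17 of them lower with normal rearing. CG14500, a gene of unknown function (2R from 18188978 to 18189654), averaged 1.01 CPM in normally reared and 213 CPM in axenic yw. LysS, a digestive lysozyme, averaged 0.777 and 136 CPM, and Cyp4p2, a cytochrome P450, 1.79 and 204 CPM. Culd, a gene of unknown function in the gut, went the other way, with 425 and 28.4 CPM, as did Syt4, a synaptotagmin of vesicle release, with 27.5 and 0.0835 CPM. For 24 of the 25 genes the 15 normally reared 50-base yw midguts lay nearer to the axenic 76-base yw. CG14500 had 268 CPM there, LysS 223 and Culd 15.2. Axenic 76-base yw and 50-base yw differed by this rule in 4 genes, and normally reared and axenic 76-base mutants in 3. Differences of these 25 genes are therefore given below as differences from the yw libraries used.

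**Figure D2:**
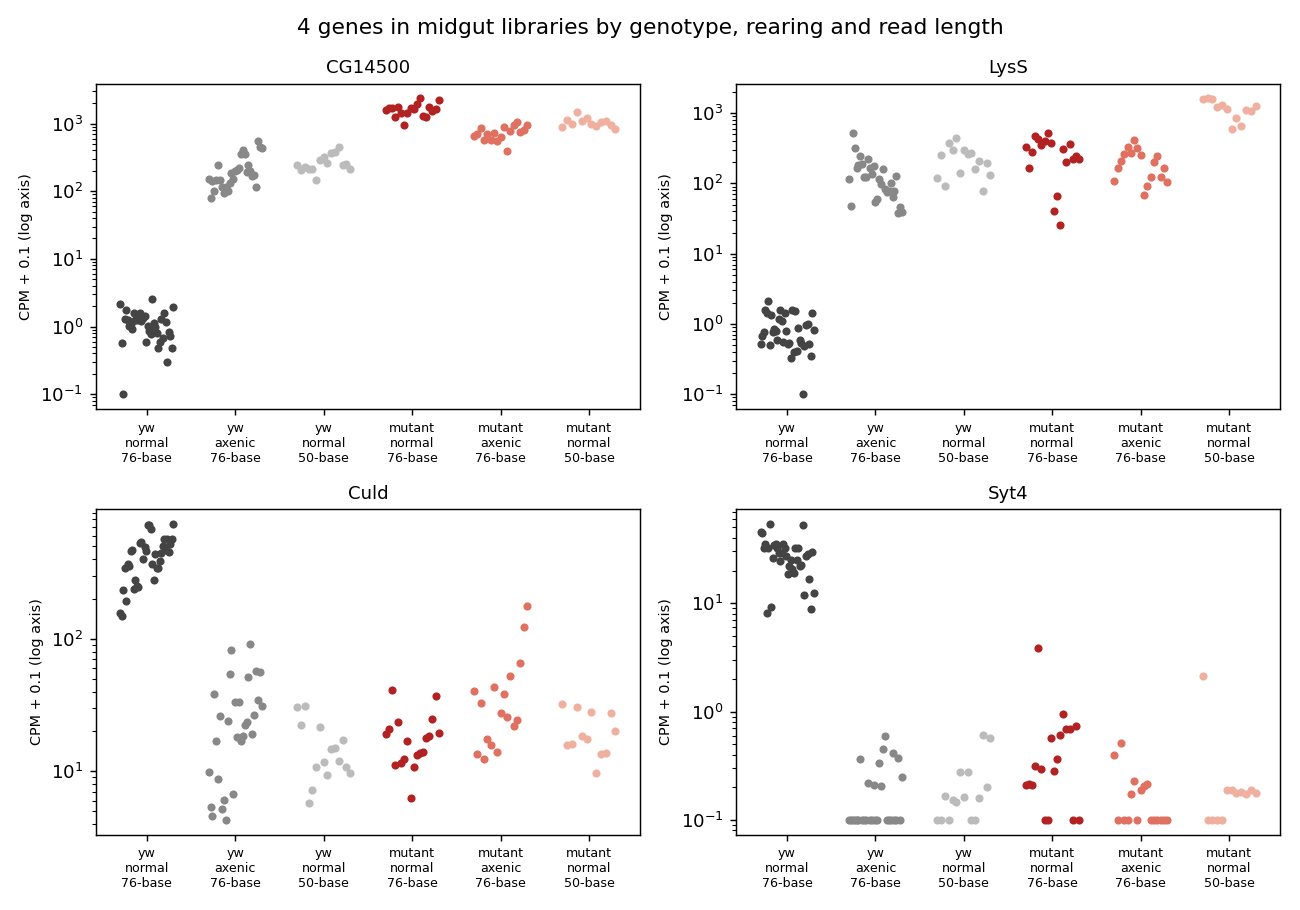
CG14500, LysS, Culd and Syt4 in CPM plus 0.1 on a log axis, with a point for each midgut library, by genotype, rearing and read length. Normally reared 76-base yw averaged 1.01 CPM of CG14500, whereas 50-base yw, also normally reared, averaged 268.

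Which midgut transcripts the loss of AhcyL1 changes in young flies was asked at 7 d in 76-base midguts of both sexes. P450 and glutathione transferase genes were more often lower than higher in the libraries labelled mutant, which did not hold in axenic midguts (below). Of 8308 genes tested, 428 rose and 456 fell, 484 of them at least 2-fold, and 875 had the same sign in both sexes. Limma on the authors' FPKM, an alternative added after the data were seen, called 1262 up and 226 down. CG14500 rose by 9.76 ± 0.35 (adjusted p = 1.5e-11), LysS by 7.88 ± 0.30 and Cyp4p2 by 5.16 ± 0.23, all from the low yw levels above. Cyp6d2, another P450, rose by 3.17 ± 0.21 (adjusted p = 3.5e-08). CG13313, of unknown function (3L from 8958857 to 8960921), fell by 6.33 ± 0.35, from 51.0 ± 8.64 to 0.578 ± 0.0124 CPM in males. Cyp4p1 fell by 2.96 ± 0.26, Cyp12a4, a mitochondrial P450, by 1.79 ± 0.19, and the glutathione transferase GstE7 by 2.39 ± 0.30 (adjusted p = 4.6e-05). RnrL, the large subunit of ribonucleotide reductase (2L from 10325026 to 10327943), did not pass at 1.53 ± 0.51 (adjusted p = 0.066), nor did RnrS, the small subunit, at 0.61 ± 0.20 (adjusted p = 0.067). Both passed in DESeq2, in limma on FPKM and without yw females replicate 1, and over all alternatives their adjusted p ranged from 0.028 to 0.19 and from 0.0093 to 0.17.

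Of 63 cytochrome P450 genes, 3 rose, 20 fell and 40 did not pass (4 up and 23 down adjusted over the list alone; adjusted p = 0.5 with an estimated correlation). Of 30 glutathione transferases, 8 fell and none rose (1 up and 12 down adjusted over the list alone; adjusted p = 0.8 with an estimated correlation). The oxidative stress list, which shares genes with both, had 8 of 27 lower. In the visceral muscle list 5 of 16 fell, among them Prm (paramyosin) and Act57B (an actin), neither of which passed in limma on FPKM, against 11 adjusted over the list alone. Of 15 stem cell and enteroblast markers, 4 rose and none fell (8 up adjusted over the list alone), and without the libraries with transcripts of other tissues 2 of 16 rose (3 adjusted over the list alone). Sox21a, a factor of enteroblast differentiation, rose by 1.47 ± 0.22 (adjusted p = 0.0003), and Egfr, the growth factor receptor of stem cells, by 1.30 ± 0.22. These 3 lists had an adjusted p of 0.5 with an estimated correlation. Of 32 trypsins and other serine proteases 4 rose and 5 fell (4 up and 11 down adjusted over the list alone), and camera did not call the list (adjusted p = 0.41). No gene of the cell cycle list (26 tested), the enterocyte identity list (15), the insulin list (15), the Malpighian tubule list (9) or the ribosomal protein list (79) passed in edgeR. The library of yw males replicate 1 carried testis transcripts. Without the libraries with transcripts of other tissues the count was 706, and the cell cycle list changed its call. Of 20 cell cycle genes then tested 5 rose and none fell (10 up adjusted over the list alone), and the adjusted p of the list was 1.2e-06 against 0.12 with all libraries.

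The rescue was compared with the mutant at 7 d. AhcyL1 rose by 1.02 ± 0.12 (adjusted p = 3.4e-05). Here 195 genes rose and 365 fell. Amyrel, an amylase relative (2R from 16651095 to 16652699), fell by 6.62 ± 0.39, from 240 ± 45.3 to 1.92 ± 0.906 CPM in females. Amy-p, the proximal amylase, fell by 2.03 ± 0.21, LManIV, a lysosomal mannosidase, by 3.45 ± 0.27, and the lipase Lip3 by 4.16 ± 0.34. Of 23 genes of carbohydrate and lipid digestion, 15 fell and none rose (17 down adjusted over the list alone; adjusted p = 0.15 with an estimated correlation). Of 30 glutathione transferases 11 fell, GstD8 by 2.37 ± 0.33 (1 up and 15 down adjusted over the list alone; adjusted p = 0.89 with an estimated correlation). Neither list was reversed, as 4 digestion genes rose and 8 fell in the mutant, and 8 transferases fell. Cyp6a2, a P450 of insecticide metabolism, rose by 3.51 ± 0.47 (adjusted p = 0.00015), and phr, a DNA photolyase, by 4.03 ± 0.29. RnrS fell by 0.87 ± 0.20 (adjusted p = 0.014), with an adjusted p of 0.05 to 0.052 without rescue females replicate 1 or 2 or rescue males replicate 3. No cell cycle gene passed in edgeR on all libraries. Without the libraries with transcripts of other tissues 2 of 20 fell (10 adjusted over the list alone), with a list adjusted p of 1.9e-05 against 0.41.

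Of the 884 genes changed in the mutant at 7 d, 172 changed the other way in the rescue, against 18.8 up and 10.7 down for independent lists, and 61 went further in the same direction. Both comparisons share the mutant libraries, which alone makes fold changes oppose each other. Their correlation across genes, which are not independent replicates, was -0.40, against -0.49 in data simulated with no change and 0.02 with the mutant libraries parted between the comparisons. Parting left 202 and 206 called genes and 29 that changed the other way. Some mutant differences stayed in the rescue. By the 8-fold rule, 4 genes parted all 73 mutant and rescue midguts from all 80 yw midguts. CG13313 and Burs, a subunit of the hormone bursicon, were lower. Dscam4, a cell adhesion gene (3L from 8238647 to 8282398), and the protease CG11841 were higher. CG13313 did not exceed 0.975 CPM in any mutant or rescue midgut and was at least 4.95 CPM in every yw midgut.

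Whether the 7 d response differs between the sexes was tested as an interaction. Few genes passed (3 up and 9 down). Jon25Bi, a serine protease of the Jonah family, differed by -3.82 (females minus males, adjusted p = 0.016). It went from 3350 CPM in yw to 1270 in mutant females and from 338 to 1360 in males. Jon25Bii, its neighbour, differed by -3.59 (adjusted p = 0.017), with 1570 and 531 CPM in females and 216 and 656 in males. The call of Jon25Bii was lost without any of 6 of the 12 libraries (0.052 to 0.072) and with no filter (0.053), and both were lost without the libraries with other-tissue transcripts (0.069 and 0.13). In edgeR 0 genes passed without yw females replicate 2, where 446 had an unadjusted p under 0.05. Of 32 trypsins and other serine proteases, 2 passed, both lower (9 down adjusted over the list alone; adjusted p = 0.39 with an estimated correlation).

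At 40 d, over both sexes, mutant midguts had more transcripts of DNA replication (lower in females) and serine proteases (lower in males) than yw. P450s, glutathione transferases and copper cell genes were lower. Of 8678 genes, 1691 rose and 1891 fell, 943 at least 2-fold, and AhcyL1 fell by 0.55 ± 0.08 (adjusted p = 2.3e-05). PCNA, the sliding clamp of replication, rose by 1.63, and RnrL rose by 1.34 ± 0.16 (adjusted p = 6.1e-06). Both rises lay in males, where PCNA rose by 3.35 and RnrL by 3.01, from 4.46 CPM in yw to 40.8. In females neither passed, PCNA at -0.10 (adjusted p = 0.70) and RnrL at -0.33 (adjusted p = 0.24), with 29.7 CPM against 40.0 in yw. Jon99Fi, a Jonah protease with a near-identical copy in Jon99Fii, rose by 4.15 ± 0.19. AstC, the peptide hormone allatostatin C, rose by 1.29. Cyp4p1 fell by 3.42 ± 0.14, GstE6 by 2.36 ± 0.15 and MtnD, a metallothionein that binds copper, by 3.24. CG14500 rose by 10.90 ± 0.32 and Syt4 fell by 7.21 ± 0.26, from the yw levels above.

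Of 29 cell cycle and replication genes, 22 rose and none fell (23 up adjusted over the list alone; adjusted p = 0.36 with an estimated correlation). Of 62 cytochrome P450 genes, 5 rose and 41 fell (7 up and 43 down adjusted over the list alone), and this call held with an estimated correlation at an adjusted p of 0.049. Of 32 trypsins and other serine proteases 16 rose and 4 fell, and of 24 enteroendocrine markers 12 rose and 2 fell, both counts alike adjusted over the list alone. Of 32 glutathione transferases 14 fell and 2 rose, and of 27 oxidative stress genes 14 fell and 2 rose, with no other count adjusted over the list alone. Copper cell genes, of the acid-secreting midgut region, had 8 of 10 lower and 1 higher, and 3 of 7 fat body genes fell (4 adjusted over the list alone). Oxidative phosphorylation genes had 35 of 66 higher and 3 lower (37 and 3 adjusted over the list alone), and ribosomal protein genes 19 of 79 lower and 1 higher (11 lower adjusted over the list alone). Apart from the P450s, these lists had an adjusted p of 0.36 to 0.67 with an estimated correlation. The proteasome list, with 7 of 33 lower, had an adjusted p of 0.041, of 0.062 with a replicate block and of 0.67 with an estimated correlation. Of 14 JAK-STAT and EGF genes 6 rose, of 19 DNA damage genes 8 fell, of 16 heat shock genes 4 fell, and of 16 antimicrobial and Imd genes 5 rose and 6 fell, and camera called none of these 4 lists.

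The rescue at 40 d reversed part of this. AhcyL1 rose (adjusted p = 9.3e-09) to 212 CPM in females and 202 CPM in males. Replication genes and JAK-STAT and EGF genes fell, while proteases, P450s and ribosomal protein genes rose, with 1807 genes up and 1793 down. RnrL fell by 1.70 ± 0.16, PCNA by 1.66, upd3, an interleukin-like ligand made by stressed enterocytes, by 3.52, and Socs36E, a target of that pathway, by 2.52. Cyp6a2 rose by 4.09 ± 0.19 and MtnA, the main copper metallothionein, by 3.21. Of 29 cell cycle genes 24 fell (1 up and 25 down adjusted over the list alone), and of 14 JAK-STAT and EGF genes 7 fell (8 adjusted over the list alone). Of 32 proteases 23 rose and 1 fell, the same adjusted over the list alone, and of 62 P450s 29 rose and 9 fell (29 and 11 adjusted over the list alone). These 4 lists had an adjusted p of 0.18 with an estimated correlation. Ribosomal proteins (60 of 79 up, 68 adjusted over the list alone) and oxidative phosphorylation (20 up, 15 adjusted over the list alone) had 0.72. Of the 3582 genes changed in the mutant, 1505 changed the other way in the rescue, against 349.4 and 393.8 for independent lists, and 416 went further in the same direction. The correlation was -0.32, against -0.46 in data simulated with no change and -0.27 with the mutant libraries parted. Parting left 2503 and 2517 called genes and 850 that changed the other way.

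The 40 d response differed between females and males in 1375 genes with a positive and 1198 with a negative difference. Proteases and ribosomal proteins moved up in females relative to males, and replication genes moved up in males. RnrL differed by -3.34 ± 0.32 (females minus males), PCNA by -3.45, CycA, a mitotic cyclin, by -2.74 and upd3 by -6.43. Jon99Fi differed by 5.37, ninaD, a scavenger receptor that takes up carotenoids, by 11.69, and MtnA by 4.75. Of 29 cell cycle genes 25 were lower in females relative to males (26 adjusted over the list alone), and of 32 proteases 23 were higher (24 adjusted over the list alone), both with an adjusted p of 0.11 with an estimated correlation. All but 3 of 79 ribosomal protein genes were higher, 76 of them (76 adjusted over the list alone; adjusted p = 0.36 with an estimated correlation).

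Axenic flies were compared to ask what the mutation does without microbes. At 7 d, AhcyL1 fell by 0.92 ± 0.11 (adjusted p = 2.7e-06), and 355 genes rose and 404 fell. Stem cell markers and heat shock genes rose, and copper cell genes fell. Dscam4 rose by 5.14 ± 0.37, CG31233, an aminopeptidase, by 4.02 ± 0.17, from 143 to 3490 CPM in females, and GstD2, a glutathione transferase, by 3.94. The small heat shock genes Hsp23 and Hsp27 rose by 2.98 and 2.58. Egfr rose by 1.80 and mira, an adaptor of asymmetric stem cell division, by 1.42. CG13313 fell by 6.97 ± 0.33, the metallothionein MtnD by 3.93 ± 0.34, and Muc14A, a mucin, by 7.98. RnrL did not pass at 0.59 ± 0.38 (adjusted p = 0.48). Of 16 stem cell markers 7 rose (8 adjusted over the list alone; adjusted p = 0.055 with an estimated correlation). Of 16 heat shock and unfolded protein genes 6 rose (8 adjusted over the list alone), and this call held with an estimated correlation. Of 10 copper cell genes 4 fell (4 adjusted over the list alone; adjusted p = 0.06 with an estimated correlation).

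In axenic rescue against axenic mutant midguts at 7 d, AhcyL1 rose by 1.31 ± 0.12 (adjusted p = 2.2e-08), and 234 genes rose and 223 fell. Muscle genes and heat shock genes fell. CG11034, a dipeptidyl peptidase, fell by 8.39 ± 0.33, from 534 to 1.16 CPM in females, Hsp27 by 2.89 and RnrS by 0.79 (adjusted p = 0.0066). There phr rose by 4.99 ± 0.31 (axenic mutants averaged 0.802 CPM, axenic yw 1.06). Of 16 visceral muscle genes 9 fell (13 adjusted over the list alone), which held with an estimated correlation at an adjusted p of 0.031. Of 16 heat shock genes 4 fell (7 adjusted over the list alone; adjusted p = 0.12 with an estimated correlation). Proteases rose, 8 of them (13 adjusted over the list alone; adjusted p = 0.37 with an estimated correlation).

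Axenic mutants at 40 d had fewer protease transcripts and more of stem cell and replication genes than axenic yw. AhcyL1 fell by 0.67 ± 0.09 (adjusted p = 9.3e-06), and 1299 genes rose and 1334 fell. Of 32 trypsins and other serine proteases 1 rose and 23 fell, which held with an estimated correlation at an adjusted p of 0.015. Dscam4 rose by 4.57 ± 0.17, vkg, a collagen of the gut's basement membrane, by 4.63 and Jabba, a lipid droplet protein, by 4.60. CG13313 fell by 7.79, MtnD by 5.12 ± 0.24 and otu, a deubiquitinase of the germline, by 6.99 ± 0.26. RnrL rose by 0.87 (adjusted p = 0.0039, and 0.085 without mutant males replicate 2) and RnrS by 0.47 (adjusted p = 0.0035). Of 16 stem cell markers 11 rose (12 adjusted over the list alone; adjusted p = 0.063 with an estimated correlation), and of 29 cell cycle genes 17 rose (19 adjusted over the list alone; adjusted p = 0.18 with an estimated correlation). In the rescue, AhcyL1 rose by 1.06 ± 0.09 (adjusted p = 3.5e-08), and 594 genes rose and 423 fell, 674 in all without mutant males replicate 2. Of 32 proteases 16 rose (17 adjusted over the list alone), which held with an estimated correlation at an adjusted p of 0.013. RnrS fell by 0.63 (adjusted p = 0.00088), and kek1, an inhibitor of the EGF receptor, by 5.76. Oxidative phosphorylation genes had 12 of 67 higher (40 adjusted over the list alone; adjusted p = 0.7 with an estimated correlation).

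Axenic and normally reared yw were compared at both ages, which cannot part microbes from the yw sets. At 7 d, 569 genes were higher and 665 lower in axenic flies, a count that chance can give, since 3 of 60 splits had as many. Immune genes that answer bacteria fell, along with glutathione transferases. PGRP-SC1a, an amidase that degrades peptidoglycan (2R from 8709733 to 8710320, with a near-identical copy in PGRP-SC1b), fell by 5.70 ± 0.28, from 771 to 16.5 CPM in females. PGRP-SC2, its relative, fell by 2.27. Of 14 antimicrobial and Imd genes 10 fell (1 up and 11 down adjusted over the list alone; adjusted p = 0.064 with an estimated correlation). Of 32 glutathione transferases 16 fell (18 adjusted over the list alone; adjusted p = 0.54 with an estimated correlation). Of 23 genes of carbohydrate and lipid digestion 14 fell and 3 rose, with the same counts adjusted over the list alone and an adjusted p of 0.54 with an estimated correlation. CG14500 (7.35 ± 0.30) and Cyp4p2 (6.06 ± 0.21) were higher in axenic yw, and averaged 268 and 72.2 CPM in normally reared 50-base yw. The fall of 9 of 24 cell cycle genes (adjusted p = 0.8 with an estimated correlation) rested on yw males replicate 1, and without the libraries with other-tissue transcripts its adjusted p was 0.096.

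At 40 d 2006 genes were higher and 2180 lower in axenic yw. Serine proteases rose, and proteasome, replication and immune genes fell. Jon99Fi rose by 4.19 ± 0.16 and Jon66Ci, another protease, by 8.79. PGRP-SD, a sensor of bacteria, fell by 2.26, GstD8 by 3.51, RnrL by 1.12 (adjusted p = 0.00018) and RnrS by 0.82. Of 32 proteases 27 rose and 1 fell (27 and 2 adjusted over the list alone), which held with an estimated correlation at an adjusted p of 0.0015. Proteasome genes fell in 32 of 33 (32 adjusted over the list alone; adjusted p = 0.38 with an estimated correlation). Of 29 cell cycle genes 21 fell (22 adjusted over the list alone; adjusted p = 0.36 with an estimated correlation), and of 17 antimicrobial and Imd genes 11 fell (11 adjusted over the list alone; adjusted p = 0.32 with an estimated correlation). AhcyL1 did not pass at 0.21 (adjusted p = 0.052, and 0.016 to 0.18 over the alternatives).

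Whether the mutant response at 40 d depends on rearing was tested as an interaction, axenic minus normal, with 1145 genes positive and 1166 negative. Proteases responded in opposite directions. Of 32, 23 were negative and 1 positive (24 and 1 adjusted over the list alone), which held with an estimated correlation at an adjusted p of 0.0026. Jon99Fi differed by -2.75 and Cyp4p2 by -6.70 ± 0.20, and Cyp6a20, a P450 linked to aggression, by 3.40. The interaction cannot part rearing from the yw sets, whose 25 genes include Cyp4p2 and Cyp6a20. Glutathione transferases were positive in 17 of 32 (17 adjusted over the list alone; adjusted p = 0.31 with an estimated correlation), and ribosomal proteins in 50 (61 adjusted over the list alone; adjusted p = 0.57 with an estimated correlation).

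Age was compared within normally reared yw, 40 d against 7 d. Respiratory genes and serine proteases fell with age, and stem cell and DNA damage genes rose, with 816 genes up and 1379 down. Females alone had 880 up and 1351 down and males alone 119 up and 366 down, a difference not tested. Oxidative phosphorylation genes fell in 66 of 67 (67 adjusted over the list alone; adjusted p = 0.23 with an estimated correlation). Serine proteases fell in 26 of 32 (26 adjusted over the list alone), which held with an estimated correlation at an adjusted p of 0.04, and Jon99Fi fell by 3.72 ± 0.21. Of 18 DNA damage and apoptosis genes 6 rose (6 adjusted over the list alone), which held at 0.048. Of 27 ribonucleotide reductase and nucleotide genes 9 rose and 2 fell (adjusted p = 0.09 with an estimated correlation), with RnrL up by 1.54 ± 0.34 (adjusted p = 0.0026) and RnrS by 0.75 ± 0.16 (adjusted p = 0.0013), in females by 1.67 and with no call in males (-0.16, adjusted p = 0.72). Of 16 stem cell markers 10 rose (12 adjusted over the list alone; adjusted p = 0.077 with an estimated correlation), Sox21a by 2.46 ± 0.20. ImpL2, a secreted antagonist of insulin signalling, rose by 3.85 ± 0.38, from 4.41 to 483 CPM in females and from 3.92 to 16.1 CPM in males, and Agpat1, an enzyme of phospholipid synthesis, as well (adjusted p = 4.1e-09). Ribosomal proteins fell in 56 of 79 (73 adjusted over the list alone; adjusted p = 0.54 with an estimated correlation).

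The mutant response differed between 40 d and 7 d in 61 genes, 35 positive and 26 negative. The count was 34 without yw females replicate 2 at 7 d and 136 without mutant males replicate 3 at 7 d. The Jonah protease Jon99Fii differed by 2.49 ± 0.31, Jon65Aiv by 1.91 and Jon99Fi by 1.62. Amyrel differed by -2.50 ± 0.44. Of 32 proteases 5 were positive (13 up and 1 down adjusted over the list alone; adjusted p = 0.17 with an estimated correlation). Neither RnrL (-0.12 ± 0.46, adjusted p = 0.99) nor RnrS (-0.26 ± 0.22, adjusted p = 0.80) passed.

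Deoxynucleosides feed the nucleotide pool that ribonucleotide reductase supplies, and dAdo gives rise to its inhibitor dATP. In 76-base yw midguts at 7 d, dAdo raised 86 genes and lowered 130, 54 of them at least 2-fold. Cbs, cystathionine beta-synthase, rose by 0.89 ± 0.16, from 13.0 to 43.1 CPM in females and with no call in males (0.42, adjusted p = 0.34), and Cftr, a chloride channel, by 1.08 ± 0.18. CG9864, a phosphate transporter relative, fell by 1.75 ± 0.24. Oxidative phosphorylation genes fell in 2 of 66 (34 adjusted over the list alone; adjusted p = 0.95 with an estimated correlation). RnrL (-0.31 ± 0.36, adjusted p = 0.64) and RnrS (0.46 ± 0.20, adjusted p = 0.19) did not pass. The count was 537 without yw males replicate 1 and 43 without dAdo males replicate 2.

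With dGuo, 67 genes rose and 174 fell at 7 d. The count was 92 without yw females replicate 2 and 406 without yw males replicate 3. Cbs rose by 0.78 (adjusted p = 0.017, and 0.053 without dGuo males replicate 2), from 13.0 to 53.2 CPM in females, while males had 49.4 and 42.4 CPM. The nuclease Sid rose by 1.40 ± 0.23 and Lip3 by 1.32. Idgf4, a growth factor of the chitinase family, fell by 2.44 ± 0.28, and Cyp4g1, a P450 of hydrocarbon synthesis in oenocytes, by 7.92 ± 1.12. Of 23 digestion genes 5 rose (8 adjusted over the list alone; adjusted p = 0.59 with an estimated correlation). The direct test between dAdo and dGuo called 75 genes higher and 21 lower with dAdo, 43 in all without dAdo females replicate 3. The metallothioneins MtnB (-2.15) and MtnC (-1.30) were lower with dAdo. Ctr1B, a copper importer, differed by 1.45. Hemocyte genes were higher in 4 of 8 (7 adjusted over the list alone; adjusted p = 0.11 with an estimated correlation), and fat body genes in 4 of 11 (5 adjusted over the list alone; adjusted p = 0.16 with an estimated correlation). Of the genes that dAdo changed, 32 also changed in the same direction in the 50-base mutant, against 11.1 and 21.0 for independent lists, and 29 went the other way.

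At 40 d dGuo and HU were compared with untreated yw, to ask whether they alter the aged midgut. Over both sexes, serine proteases and ribosomal proteins were higher and replication genes lower with each treatment. The 2 comparisons share untreated libraries, which alone can make them alike. With dGuo 831 genes rose and 693 fell, 969 in all without dGuo females replicate 1, a count that chance can give, since 5 of 100 splits had as many. Females alone had 1433 up and 1361 down and males alone 1 up and 1 down, a difference not tested. Jon99Fi rose by 2.61 ± 0.17, from 45.1 to 812 CPM in females and from 184 to 293 CPM in males. Over both sexes RnrL fell by 0.88 (adjusted p = 0.0097) and CycA by 1.27, and both calls came from females. RnrL fell in females by 2.31, from 40.0 to 6.38 CPM, and had 4.46 and 6.41 CPM in males (0.56, adjusted p = 0.79). CycA fell in females by 2.81 and did not pass in males (0.27, adjusted p = 0.93). Of 30 proteases 24 rose (24 adjusted over the list alone) and of 25 cell cycle genes 9 fell (14 adjusted over the list alone). Both held with an estimated correlation, at an adjusted p of 0.013 and 0.021. Of 78 ribosomal protein genes 58 rose (76 adjusted over the list alone; adjusted p = 0.39 with an estimated correlation).

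With HU at 40 d, 1468 genes rose and 1384 fell. Females alone had 1703 up and 1743 down and males alone 153 up and 110 down, a difference not tested. Agpat1 fell by 4.81 ± 0.32 and ImpL2 by 4.45 (in males by 2.13, adjusted p = 0.21), and Sox21a fell by 2.08. The scavenger receptor ninaD rose by 5.18 ± 0.27 and MtnA by 3.14. RnrL fell by 1.34 (adjusted p = 0.00022) and CycA by 1.90, in females by 2.61 and 3.26, while neither passed in males (-0.07 and -0.54, adjusted p = 0.93 and 0.29). Of 30 proteases 25 rose (25 adjusted over the list alone) and of 25 cell cycle genes 20 fell (23 adjusted over the list alone), and both held with an estimated correlation at an adjusted p of 0.014. Ribosomal proteins rose in 77 of 78 (adjusted p = 0.36 with an estimated correlation). Of 9 genes of the methyl cycle list 6 rose (6 adjusted over the list alone; adjusted p = 0.072 with an estimated correlation).

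HU in the mutant asks whether blocking the reductase undoes the mutant state. In 76-base mutant midguts at 7 d, 38 genes rose and 33 fell. Ctr1B fell by 1.89 ± 0.27 (adjusted p = 0.018). Of 16 visceral muscle genes 5 rose (14 adjusted over the list alone; adjusted p = 0.38 with an estimated correlation). No oxidative phosphorylation gene passed in edgeR, and 56 of 64 fell adjusted over the list alone (adjusted p = 0.55 with an estimated correlation). Without mutant females replicate 1 no gene passed in edgeR, where 1324 had an unadjusted p under 0.05 and Ctr1B an adjusted p of 0.058. DESeq2 on all libraries called 415. The count was 9 without mutant females replicate 2, which carried head transcripts, and 144 without mutant males replicate 3.

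In 50-base midguts of females the mutant was compared with yw at 1 d and 7 d. At 1 d, AhcyL1 fell by 1.07 ± 0.10 (adjusted p = 0.0023), and 675 genes rose and 425 fell, 392 in all without mutant replicate 2. Respiratory genes rose, as did the immune amidase PGRP-SC1a. It rose by 3.63 ± 0.23, Jon66Ci by 6.31 ± 0.69 and GstD7 by 1.32. Muc14A fell by 8.72 ± 0.50 and Ser6, a serine protease, by 1.57. Oxidative phosphorylation genes rose in 42 of 67 (46 adjusted over the list alone; adjusted p = 0.64 with an estimated correlation), and proteases in 11 of 32 with 2 lower (23 and 2 adjusted over the list alone; adjusted p = 0.68 with an estimated correlation). RnrL (-0.52 ± 0.26, adjusted p = 0.26) did not pass.

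At 7 d, AhcyL1 fell by 1.24 ± 0.13 (adjusted p = 4.1e-06), 1255 genes rose and 1395 fell (1746 in all without yw replicate 2), and both reductase subunits rose. RnrL rose by 2.15 ± 0.34, from 4.60 to 27.5 CPM (adjusted p = 0.00026), RnrS (2R from 11983145 to 11985393) by 1.74 ± 0.22, from 12.4 to 57.2 CPM (adjusted p = 2.1e-05), and PCNA rose as well (adjusted p = 0.00092). Dscam4 rose by 5.09 ± 0.25. CG13313 fell by 5.33, MtnD by 3.23, Ser6 by 2.44 and Cyp6a9 by 1.91. Of 30 cell cycle genes 24 rose and none fell (28 up adjusted over the list alone). Of 32 proteases 17 fell and 1 rose (19 and 2 adjusted over the list alone), and of 23 digestion genes 14 fell and 1 rose (15 and 1 adjusted over the list alone). P450s had 30 of 71 lower and 9 higher (33 and 10 adjusted over the list alone), and ribosomal proteins 44 of 79 lower (52 adjusted over the list alone). Hemocyte genes had 6 of 9 lower (6 adjusted over the list alone), and 6 of 19 ovary and eggshell genes were higher (7 adjusted over the list alone). These lists had an adjusted p of 0.6 to 0.63 with an estimated correlation. Of the genes called in the 76-base series, 424 changed the same way here, against 57.5 and 71.8 for independent lists, and 39 the other way.

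The 50-base rescue at 7 d raised AhcyL1 by 1.15 ± 0.13 (adjusted p = 2.8e-05), with 408 genes up and 390 down, 351 in all without rescue replicate 3. The reductase genes returned, RnrL falling by 1.40 (adjusted p = 0.015, and 0.053 to 0.092 without mutant replicate 1 or rescue replicate 1 or 3) and RnrS by 1.71 (adjusted p = 9e-05). Both phr (4.24 ± 0.32) and Cyp6a2 (3.24) rose, and Amyrel fell by 4.46. Of 30 cell cycle genes 10 fell (22 adjusted over the list alone), and of 32 proteases 12 rose (18 adjusted over the list alone), both with an adjusted p of 0.7 with an estimated correlation. Insulin and TOR genes rose in 4 of 17 (6 up and 1 down adjusted over the list alone; adjusted p = 0.29 with an estimated correlation).

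HU at 7 d changed yw and mutant females differently in the 50-base series. In yw 401 genes rose and 524 fell, 316 in all without yw replicate 2. Muscle genes rose, and proteases and other digestive genes fell. Mhc rose by 1.83 ± 0.19, from 138 to 644 CPM, and GstD2 by 3.18. LManIV fell by 1.73 ± 0.20, Rel, the transcription factor of Imd signalling, by 0.83, and pirk, an inhibitor of that pathway, fell as well (adjusted p = 0.011, and 0.052 without HU replicate 1). Visceral muscle genes rose in 14 of 16 (15 adjusted over the list alone; adjusted p = 0.23 with an estimated correlation), and proteases fell in 12 of 32 (24 adjusted over the list alone; adjusted p = 0.48 with an estimated correlation). Of 23 genes of carbohydrate and lipid digestion 8 fell (9 adjusted over the list alone; adjusted p = 0.47 with an estimated correlation), and of 18 antimicrobial and Imd genes 5 fell (1 up and 7 down adjusted over the list alone; adjusted p = 0.48 with an estimated correlation). In the mutant 2 genes passed, both up: tim, the clock gene timeless, by 1.13 ± 0.14, and CG32407, of unknown function, by 1.25 ± 0.16. DESeq2 called 89, and 913 genes had an unadjusted p under 0.05. With 2 called genes, whether HU reverses the changes of the 76-base mutant cannot be read from shared calls. The test of the difference called 398 genes positive and 193 negative, 174 in all without yw replicate 2. Mhc differed by -1.86 ± 0.26, Mmp2, a matrix protease, by -3.67 and LManIV by 2.69. Visceral muscle genes differed in 10 of 16, all negative (15 adjusted over the list alone; adjusted p = 0.35 with an estimated correlation).

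In the same series dAdo raised 583 genes and lowered 646 in yw, 502 in all without dAdo replicate 2. Of 19 ovary and eggshell genes 7 rose and none fell (10 up adjusted over the list alone; adjusted p = 0.63 with an estimated correlation), among them the chorion gene Cp38 by 5.50 ± 1.29 (adjusted p = 0.012, and 0.051 without yw replicate 2). CG9864 rose by 2.70 ± 0.34, from 62.9 to 388 CPM, opposite to its fall in the 76-base series, and the difference between the series was not tested. Tsf1, transferrin, fell by 3.36 and GstD8 by 1.40. Ribosomal proteins fell in 40 of 79 and 1 rose (62 and 1 adjusted over the list alone), and glutathione transferases fell in 10 of 32 (16 adjusted over the list alone), both with an adjusted p of 0.59 with an estimated correlation. In the mutant dAdo raised 12 genes and lowered 41, a count of 53 that was 2 without dAdo replicate 1 and 98 without dAdo replicate 2. The clock gene tim rose by 1.75 ± 0.14, from 145 to 519 CPM (adjusted p = 2.1e-06). PGRP-SC1a fell by 2.83 ± 0.39 (adjusted p = 0.0041, and 0.059 without mutant dAdo replicate 1). Immune genes fell in 4 of 18 (5 adjusted over the list alone; adjusted p = 0.058 with an estimated correlation), and no Malpighian tubule gene passed in edgeR (adjusted p = 0.52 with an estimated correlation). Genes of other tissues fell as well. Of 19 ovary and eggshell genes 2 fell (9 adjusted over the list alone; adjusted p = 0.42 with an estimated correlation), Vm34Ca by 6.44 (adjusted p = 0.049, and 0.053 to 0.33 without each library in turn) and dec by 5.19 (adjusted p = 0.043, and 0.081 to 0.28 without 5 of the 6 libraries). Of 16 visceral muscle genes 2 fell (1 up and 13 down adjusted over the list alone; adjusted p = 0.25 with an estimated correlation), Mhc by 1.07 (adjusted p = 0.014, and 0.072 to 0.093 without 4 of the 6 libraries). RnrL (-0.28 ± 0.31, adjusted p = 0.74) and RnrS (-0.58 ± 0.21, adjusted p = 0.24) did not pass. The difference between the genotypes was not tested.

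Whole females were compared at 7 d. Photoreceptor genes were far lower in libraries labelled mutant than in yw. P450, hemocyte and enteroendocrine genes fell too, though whole flies cannot place these in the gut. AhcyL1 did not pass at 0.19 (adjusted p = 0.17, and 0.032 by DESeq2 to 0.44 over the alternatives). Of 10263 genes, 244 rose and 1121 fell, 631 in all without mutant replicate 1 and 2395 without yw replicate 2. The opsin gene ninaE (3R from 19886255 to 19888206) fell by 7.42 ± 0.46, from 608 to 3.76 CPM, and the arrestin Arr1 by 7.49, from 176 to 1.09 CPM. In whole females at 1 d, a group outside the comparisons, ninaE had stood at 1330 ± 59.9 CPM in the mutant and 1105 ± 160 in yw (n = 3 each), and in whole males at 7 d it was 96.7 in the mutant and 248 ± 205 in yw. The neuronal genes nSyb (from 26.0 to 5.85 CPM), brp (15.3 to 3.96) and elav (adjusted p = 0.016) fell too, and rose in the rescue by 2.18, 1.72 and 0.93. Cyp4d21, a P450 of the male mating circuit, fell by 6.88, and PPO1, a prophenoloxidase of crystal cells, by 2.54. Dscam4 rose by 3.95 and tobi, a glucosidase controlled by insulin, by 7.05. Of 14 head and photoreceptor genes 13 fell (13 adjusted over the list alone; adjusted p = 0.43 with an estimated correlation). Enteroendocrine markers fell in 11 of 20 (13 adjusted over the list alone), P450s in 20 of 77 with 1 higher (27 and 2 adjusted over the list alone), and hemocyte genes in 5 of 10 (5 adjusted over the list alone), each with an adjusted p of 0.84 with an estimated correlation. In the rescue 719 genes rose and 201 fell, 381 in all without mutant replicate 1, and AhcyL1 rose by 0.85 ± 0.08 (adjusted p = 0.00074). There ninaE rose by 7.29 and Arr1 by 7.52. Head genes rose in 13 of 14 (13 adjusted over the list alone; adjusted p = 0.33 with an estimated correlation).

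**Figure D3:**
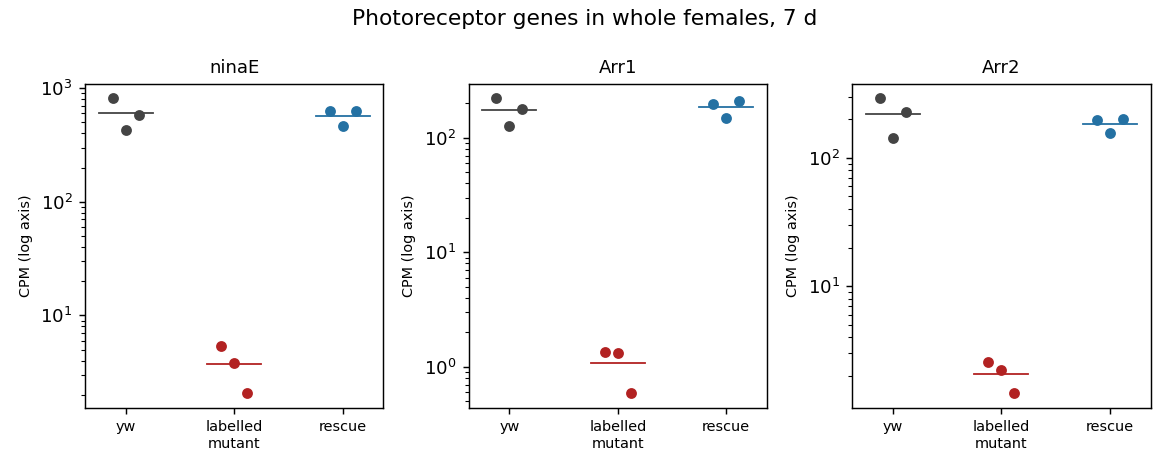
The photoreceptor genes ninaE, Arr1 and Arr2 in CPM on a log axis in whole females at 7 d, with points for libraries and lines for group means. The libraries labelled mutant averaged 3.76 CPM of ninaE against 608 in yw.

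Whole mutant males had less AhcyL1 (37.0 ± 10.2 against 89.7 ± 4.33 CPM), a fall by 1.52 ± 0.14 (adjusted p = 1.5e-05). Genes of respiration, the methyl cycle and hemocytes fell, with 606 genes up and 1361 down, 1147 in all without yw replicate 1. Sam-S, which makes S-adenosylmethionine, fell by 1.27, Gnmt, which consumes it, by 1.60, and Lsp2, a storage protein of the fat body, by 3.92. Oxidative phosphorylation genes fell in 62 of 89 (63 adjusted over the list alone). Methyl cycle genes fell in 5 of 9, AhcyL1 among them, and 1 rose. Proteases fell in 11 of 30 and hemocyte genes in 7 of 10. Apart from the first, counts were alike adjusted over the list alone. Each list had an adjusted p of 0.51 with an estimated correlation. Of 19 testis and accessory gland genes 1 fell. RnrL (0.40 ± 0.26, adjusted p = 0.33) did not pass. In the rescue AhcyL1 rose by 1.91 ± 0.14 (adjusted p = 4.7e-06) to 134 CPM, with 327 genes up and 210 down, 261 in all without rescue replicate 1. Gnmt rose by 1.83, NimC1, a phagocytic receptor of hemocytes, by 3.80 and GstE5 by 2.49. Proteases rose in 7 of 30 (13 adjusted over the list alone; adjusted p = 0.59 with an estimated correlation) and hemocyte genes in 4 of 10 (7 adjusted over the list alone; adjusted p = 0.5 with an estimated correlation).

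In whole yw males fed dAdo or dGuo, edgeR called 0 of 13389 genes for dAdo, for dGuo and for dAdo against dGuo. DESeq2 called 3, 3 and 1, and 500, 552 and 217 genes had an unadjusted p under 0.05. RnrL did not pass, at 0.33 ± 0.28 with dAdo, -0.21 ± 0.28 with dGuo and 0.54 ± 0.27 for dAdo against dGuo (adjusted p = 1).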

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

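The tests on the yw sets, the brain genes in whole females as a further test of heads, the test of counts taken by a few genes, and the test that leaves out libraries with transcripts of other tissues, were chosen only after the results were seen.

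The effect of the mutation differed between groups in 4 tests of the difference itself, and the effect of HU in 1. Between females and males at 7 d it differed in 12 genes, and at 40 d in 2573. At 7 d another split reached 502 genes, although only 3 of 100 had as many as the real one. It reversed the genotype of most male libraries and left the females as they were, so that it counted the mutant effect that both sexes share. At 40 d the highest of the other splits drawn had 1787, so chance is unlikely. Between axenic and normal rearing at 40 d the mutant effect differed in 2311 genes against 991. Chance is unlikely, and a difference between the yw sets cannot be excluded. Between 40 d and 7 d it differed in 61 genes. There 3 of 100 splits had as many, and the highest, with 1380, reversed the genotype of all females and most males at 7 d, so that it counted the mutant effect of both ages together. The effect of HU in 50-base females differed between mutant and yw in 591 genes against 556, and chance is unlikely. The split with 556 amounts to exchanging 1 HU with 1 control library of the mutant and leaves yw as labelled.

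ERCC spike-in reads, which no comparison used, made up a median of 0.142% of counts in the 50-base midgut libraries, all labelled as having no spike-in. The 2 libraries placed in no group had none.

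The 25 genes that part normally reared from axenic 76-base yw midguts are the first pattern. Microbes as the cause are argued against, because in 24 of the 25 genes the normally reared 50-base yw midguts, though raised on another food, lay nearer to the axenic ones, and normally reared and axenic mutants differed in 3 genes by the same rule. Mutant libraries under a yw label are argued against as well, since 36 of 36 normally reared yw libraries had more CG13313 than every mutant or rescue midgut. Another yw stock or an unlabelled difference in rearing other than microbes may lie behind the sets. Neither is settled, since the genes lie on 5 chromosome arms, a value that decides nothing, and no biological explanation beyond rearing was tested.

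In whole females labelled mutant at 7 d, ninaE stood at 3.76 CPM and Arr2 at 2.08 CPM, against 608 and 221 CPM in yw. A few genes taking most of the counts are argued against, with a median log2 ratio of 0.02 over all genes on library totals. A wrong genotype label is argued against, as 3 of 3 libraries scored above every whole yw female on genes that separate mutant from yw in midguts. Heads scarce in the RNA stay open, because the values point both ways. The antennal genes tested had a median change of -0.6 (9 of 10 lower, from -1.39 to 0.49), at 0.397 to 9.53 CPM in yw. The brain genes tested (Ilp5, Hug, Pdf and Dsk) had a median of -3.91 (4 of 4 lower, from -5.78 to -0.54), at 0.731 to 2 CPM in yw, the neuronal genes elav, nSyb and brp one of -2, and Ilp2, a hormone of the brain, had 128 counts over the yw libraries and 0 over the mutant ones. Whether the antennal genes are also transcribed outside the head, which would void their test, is not shown by these files. A loss of photoreceptor transcripts between 1 d and 7 d may be part of the pattern, since mutant females at 1 d had 1330 CPM of ninaE, but would not by itself lower brain genes. Other conditions particular to these 3 libraries stay open and were not tested, and AhcyL1 there was 117.4% of yw but 44.4% at 1 d.

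AhcyL1 in 76-base midguts labelled mutant at 7 d did not pass, with a change of -0.31 over both sexes against -0.92 in axenic midguts. In females it was at 104.1% of yw on library totals and changed by -0.36 with TMM. Wrong labels are argued against, because 6 of 6 libraries labelled mutant scored above all 6 labelled yw (-0.08 to 0.22 against -1.34 to -1.04) on 51 genes that separate the genotypes in axenic and 50-base libraries. RNA from other tissues is argued against as the whole cause, since without the libraries that carry it the change was -0.38 ± 0.13, still 3.1 standard errors from the axenic one. On library totals the mutant females had 83.5 CPM and yw 80.2 CPM, against 79.8 and 138.4 CPM in 50-base females. Why the change was smaller here was not tested.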

How the results depend on the processing

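Limma on FPKM and the counts without libraries that carry other-tissue transcripts were chosen only after the results were seen. The other alternatives were planned.

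RLE scaling kept 41 of 42 counts of genes within 1.5 times the reported count, the replicate block 40 of 42, no filter on low counts 32 of 41 and DESeq2 24 of 41. The genes whose mutant change HU opposed numbered 0 in edgeR, where 2 called genes leave 0.1 for independent lists, against 1 with RLE, 1 with the replicate block and 23 with DESeq2. RLE moved the median of all genes by at most 0.03. No paired analysis was planned, because the labels do not say that replicates of different groups belong together. As a check, replicate number was a block. Correlations between libraries of equal number lay from -0.34 to 0.55, and in 1 of 36 comparisons, dAdo in 50-base yw, every pair was above 0.1. The block gave 625 genes for the 50-base mutant at 1 d.

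Without the filter, where more genes share the adjustment, the difference of the sexes at 7 d had 1 gene, the mutant effect by age 35, dAdo 77, dGuo 121 and dAdo against dGuo 54 at 7 d, the HU effect by genotype 390, dAdo in the 50-base mutant 28, rescued genes at 7 d 97, and genes shared by mutant and dAdo 8. DESeq2 called more, and the cause was not tested. It gave 862 for the rescue at 7 d, 45 for the difference of the sexes at 7 d, 202 for the mutant effect by age, 779 for dAdo, 680 for dGuo, 238 for dAdo against dGuo, and 415 for HU in the mutant. In 50-base midguts it gave 89 for HU in the mutant, 915 for HU by genotype and 170 for dAdo in the mutant. In whole females it gave 2080 for the mutant and 1535 for the rescue, in whole males 3 for dAdo, 3 for dGuo and 1 for the difference of these, and 124 genes shared by mutant and dAdo. Limma on FPKM gave 1488 for the mutant at 7 d, of which 570 were among the 884 reported. The cause was not tested.

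Without the libraries with other-tissue transcripts, dAdo at 7 d called 537 genes, HU in the mutant 9, the difference of the sexes 0 (291 at an unadjusted p under 0.05), and mutant and dAdo shared 120. Of 255 lists in 10 comparisons, 19 were then newly called and 9 no longer. Among the new ones was the cell cycle list at 7 d, up in the mutant (adjusted p = 1.2e-06) and down in the rescue (1.9e-05). Lists called with the preset correlation numbered 306, and 13 with an estimated correlation, which lowers the calls because it lets genes of a list vary together. With the block the proteasome list at 40 d had an adjusted p of 0.062, copper cell genes in dAdo against dGuo 0.083, and proteases with dGuo at 7 d 0.069.

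Leaving out 1 library at a time kept 275 of 365 counts within 1.5 times. The difference of the sexes at 7 d ranged from 0 (without yw females replicate 2) to 16 genes, the axenic rescue at 40 d from 674 (without mutant males replicate 2) to 1090, and the mutant effect by age from 34 (without yw females replicate 2 at 7 d) to 136 (without mutant males replicate 3 at 7 d). At 7 d dAdo ranged from 43 (without dAdo males replicate 2) to 537 (without yw males replicate 1), dGuo from 92 (without yw females replicate 2) to 406 (without yw males replicate 3), and dAdo against dGuo from 43 (without dAdo females replicate 3) to 89. At 40 d dGuo ranged from 969 (without dGuo females replicate 1) to 1587. HU in the mutant ranged from 0 (without mutant females replicate 1) to 144 (without mutant males replicate 3).

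In 50-base midguts the mutant ranged from 392 (without mutant replicate 2) to 888 at 1 d and from 1746 (without yw replicate 2) to 2454 at 7 d, and the rescue from 351 (without rescue replicate 3) to 690. HU in yw ranged from 316 (without yw replicate 2) to 1126, HU by genotype from 174 (without the same library) to 727, dAdo in yw from 502 (without dAdo replicate 2) to 1033, and dAdo in the mutant from 2 (without dAdo replicate 1) to 98 (without dAdo replicate 2). In whole females the mutant ranged from 631 (without mutant replicate 1) to 2395 (without yw replicate 2) and the rescue from 381 (without mutant replicate 1) to 716. In whole males the mutant ranged from 1147 (without yw replicate 1) to 1573 and the rescue from 261 (without rescue replicate 1) to 430. For dAdo and for dAdo against dGuo there the range was 0 to 1, the 1 without dAdo replicate 2. Fewer libraries lower the power of each test. The other ranges stayed within 1.5 times the reported count, such as 599 to 909 for the mutant at 7 d and 3214 to 3500 at 40 d.

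Of 198 genes that the report names in a comparison, 181 passed, 173 of these passed in every other alternative run for them and 167 without each library in turn. No named gene changed direction. Depth limits the smallest libraries most, with 2482454 reads in the smallest 76-base midgut library.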

Other observations

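Here the test that leaves out an untreated yw library and the gene values of the unplaced libraries were chosen only after the result was seen.

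In 50-base midguts RnrL rose by 2.15 and RnrS by 1.74 in the mutant at 7 d, along with 24 of 30 cell cycle genes, and fell by 1.40 and 1.71 in the rescue. In the 76-base rescue at 7 d RnrS fell, a call lost without any of 3 libraries. No cell cycle gene passed there, but the list fell without other-tissue libraries (adjusted p = 1.9e-05). In old males RnrL was at 40.8 CPM in the mutant and 4.46 in yw, and in old females at 29.7 and 40.0. Relative to males 25 of 29 cell cycle genes moved down in females, so the 22 of 29 called over both sexes are a mean of unlike responses. Both subunits are S phase transcripts, so these data do not part a reductase response to loss of its inhibitor from more dividing cells. HU called 2 genes in 50-base and 71 in 76-base mutants in edgeR (89 and 415 in DESeq2), which does not test a return to yw.

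Across 5 comparisons of mutant with yw (7 d and 40 d, normal and axenic, and the 50-base series at 7 d), 147 genes were called in the same direction every time. At least 1 rescue comparison called back 78 of them, and none the other 69. Variants linked to the mutant chromosome 3, which carries AhcyL1, were a candidate source of the latter. Of the 69 genes 44.9% lay on chromosome 3, of the 78 genes 35.9%, and of all genes tested 44.3%. The ratio of 1.25 (two-sided Fisher exact p = 0.31) leaves this open. The clock gene tim rose in 50-base mutants with HU by 1.13 and with dAdo by 1.75, and the labels give no time of day.

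The 2 libraries placed in no group carry the title of yw males and the attributes of mutant females. Their lncRNA:roX1 was 252 and 446 CPM, and AhcyL1 97.2 and 112 CPM. CG13313 stood at 47.8 to 52.9 CPM and Dscam4 at 0.272 to 1.15 CPM. Of the genes that part the yw sets, Culd was at 422.0 to 601.0 CPM and CG14500 at 0 in both.

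The HU response of yw and mutant in 50-base midguts was weighed further. A larger spread between mutant libraries, which would hide the same response, is argued against, because the 925 genes called in yw had in the mutant a median change of -11.1% of that in yw (-0.08 against 0.71), and 327 had the same direction. Leaving out untreated yw replicate 2, which lowered the interaction from 591 to 174 genes (29.4%), argues against that library as the whole cause. A genotype that alters the response to HU could be behind the rest, a hypothesis from the same data.

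In whole males, exchanging the labels of dAdo replicate 2 and dGuo replicate 1 called 2829 genes where the real labels called 0 in edgeR (217 at an unadjusted p under 0.05, and 1 in DESeq2), which points to a structure of these samples. An exchange of these labels may be the source. Of the 96 genes called between dAdo and dGuo in midguts, 82.3% then had the same sign, against 67.7% with the real labels. A batch may be as well, since the libraries of another whole-male group spanned 64.2% of the gap between the exchanged sets. The tests do not choose between them, and the labels were kept.

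Regrouping the libraries tested whether chance alone gives as many genes, given here as the real count and the highest of the other splits. Chance is unlikely for the mutant at 7 d (884 and 502), 40 d (3582 and 2068), axenic 7 d (759 and 178) and axenic 40 d (2633 and 722). So it is for the rescue at 7 d (560 and 108), 40 d (3600 and 2281), axenic 7 d (457 and 71) and axenic 40 d (1017 and 442). The same holds for rearing at 40 d (4186 and 2905), dAdo at 7 d (216 and 15), dAdo against dGuo (96 and 34), HU at 40 d (2852 and 2625) and HU in the mutant at 7 d (71 and 39). Chance is less clearly unlikely for age (2195 and 2432) and dGuo at 7 d (241 and 568), as 2 and 3 of 100 splits had as many. For age the highest split amounts to exchanging yw males replicate 1 at 7 d, which carried testis transcripts, with males replicate 3 at 40 d. For dGuo it exchanges control replicate 3 with dGuo replicate 1 in both sexes, which points to a structure beside treatment. Chance cannot be excluded for rearing at 7 d (1234 and 1804), where 3 of 60 splits had as many, the highest with replicate 1 of normal and replicate 2 of axenic rearing exchanged in both sexes, or for dGuo at 40 d (1524 and 1842), where 5 of 100 had, the highest with most male labels reversed and the females as labelled.

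With 3 libraries against 3 the splits are too few. In 50-base midguts the values were 1100 and 0 for the mutant at 1 d, 2650 and 0 at 7 d, 798 and 0 for the rescue, 925 and 1 for HU in yw, 2 and 0 for HU in the mutant, 1229 and 0 for dAdo in yw, and 53 and 0 for dAdo in the mutant. In whole females they were 1365 and 0 for the mutant and 920 and 2 for the rescue, and in whole males 1967 and 0 for the mutant, 537 and 5 for the rescue, and 0 and 0 for dAdo and for dGuo, each of which 10 of 10 splits equal.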
